A study of Mus musculus with 2 samples.

How the data were processed

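Cells were taken from retinas of male CB6F1 mice aged 8 months that carry a Cx3cr1-YFP reporter, in which cells using the promoter of the fractalkine receptor gene Cx3cr1, such as microglia, are fluorescent. Per the labels' protocols, each group used 1 pool of retinas from 5 to 8 mice, which were broken up with enzymes, and live YFP-positive cells were sorted. Each pool gave 1 library of the 10x Genomics 3' end kind. The control library came from retinas without light damage. For the other library the labels' protocols describe overnight dark adaptation, dilated pupils, 4 h under LED light of 10 klux and 5 days of recovery. The authors deposited, for each library, a matrix of unique molecular identifier (UMI) counts per gene and cell barcode, together with its gene and barcode tables. Per the submitters' processing notes, Cell Ranger 2.0.0 and the mouse genome build mm10 were used; other steps are not given in the sources used here. The count values were whole numbers and were not normalized.

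The control matrix held 4003 barcodes and 20056338 UMIs, with a median of 4846 and a minimum of 1227 UMIs per barcode. The light-damaged matrix held 6821 barcodes and 58187149 UMIs, with a median of 7351 and a minimum of 3059. The lowest barcode of the light-damaged library thus lay above many barcodes of the control library, and 3216 control barcodes reached that minimum. The series text speaks of over 10000 cells; the 2 matrices held 10824 barcodes.

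Barcodes with at least 300 genes and at most 10% mitochondrial UMIs passed, 3948 of the control library and 6799 of the light-damaged library. Doublets were scored per library with Scrublet as included in scanpy. Its automatic threshold marked 0 control barcodes and 1 light-damaged barcode, under the minimum of 0.5% set beforehand, so the barcodes with the highest scores were removed instead, up to 0.8% per 1000 barcodes. This took out 128 control and 372 light-damaged barcodes and left 3820 and 6427 cells.

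UMIs were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 0.6 were used, on both libraries together and without integration. Genes of the response lists that were not cell type markers were kept out of the variable genes. Clusters were named from markers fixed before the data were examined for 18 classes, and the rule for counting markers was not fixed. The 3 rules that were tried were all written after the clusters had been seen, and the cutoffs of the rule in use were set with these cluster values in view. Under that rule, a marker counted when at least 10% of a cluster's cells had a UMI of it and its level was at least 2 times the higher of the 2 largest clusters. Levels were compared as CPM plus 10. A class other than microglia was a candidate for a cluster with 3 such markers of it. A cluster in which at least 5 of the 10 microglia markers stayed above 1/3 of the lower of those 2 clusters lost all such candidates. Of several candidates, the one with the most such markers gave the name, and a tie left the cluster unnamed. A cluster with no candidate was named microglia when at least 3 microglia markers were each seen in at least 10% of its cells, even where fewer than 5 had kept their level; the Mmp12-led cluster was named in this way. A named cluster was set back to unnamed when its 10 leading genes held more markers of another class than of its own. The same was done at a median depth under 1/3 of the median of the library with most of its cells, if no leading gene was a marker of its own class.

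UMIs were summed per library over the cells of a class and expressed as CPM, the usual scaling of counts by library total. Ratios are given with exact 95% intervals for the ratio of 2 Poisson counts, and shares of cells with exact Clopper-Pearson 95% intervals. Both cover counting error only and leave out variation between mice, pools and libraries. With 1 library per group there is no test between groups, and no p-value or standard error was computed. A fold against a count of 0 was computed against a floor of 3 counts in that library and class. For a list of genes, the median log2 ratio over members with at least 20 CPM in either library was set among 10000 random lists matched on mean expression in 20 bins, which describes these libraries only. Members over 1.5 times higher or lower were counted. Counting intervals of list medians came from 1000 Poisson draws.

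The 18 response lists were fixed before the data were examined. Of the 362 genes on all lists, 359 were in the files under the names used here; the others were not analysed here. Where 1 symbol belonged to more than 1 identifier, which was so for 56 symbols, the identifier with the most UMIs was used. Coordinates are 1-based and come from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names; 27645 of the 27998 identifiers were found there.

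Named genes followed a rule fixed before the data were examined. In microglia-like cells these were the 12 genes with the highest and the 12 with the lowest log2 ratio of CPM plus 10 among genes with at least 20 CPM in either library, the 4 members of each list with the largest absolute ratio, and genes chosen for shares of cells. In the other comparisons they were the 6 highest and the 6 lowest, and for markers of other classes the 2 with the highest CPM. Where monocyte- or macrophage-like cells were set beside microglia-like cells, genes that had shaped the clustering and cell type markers were not named. Some genes that this rule selects are not reported here. A few further list members are given as examples and were chosen after their values had been seen.

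Microglia-like cells were clustered again without any gene of the response lists. Shares of cells with a UMI were computed after each cell had been thinned at random, without replacement, to 2700 UMIs, the 10th percentile of the control microglia-like cells rounded down to a multiple of 100. Cells below that depth were left out. The ratio and list calculations were tested on simulated counts of the 2 libraries over 4948 genes. In that simulation 94.9% of the unchanged genes had their true ratio inside the interval, and so did 95.5%, 97.0% and 98.5% of genes changed by 1.5-fold, 2-fold and 4-fold, respectively. The simulated counts were Poisson draws, the model that the intervals assume, so coverage near 95% was built in. It checks the calculation only and says nothing about variation between cells, mice or libraries.

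Alternatives covered the cell filter, doublet removal, the resolution, the variable genes, the naming rule, library scaling, the expression minimum, the pseudocount, the weighting of cells, the clusters in the microglia-like class and the thinned depth. Leaving out the Mmp12-led, the interferon-led or the cycling cluster, adding unnamed clusters, keeping only deep control cells and the other naming rules were chosen after the data had been examined; the rest were fixed before the data were examined. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.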

Results

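Single-cell RNA sequencing measured the transcripts of retinal cells sorted for the Cx3cr1-YFP reporter, which marks microglia, the resident macrophages of the retina, and related myeloid cells. A control library was set beside a library from retinas taken 5 days after damaging light, a model of photoreceptor degeneration. Each group was 1 pool of 5 to 8 mice and 1 library, so no difference between the groups has a replicate check. The control library had 20056338 UMIs over all barcodes and kept 3820 cells with 19082407 UMIs. The light-damaged library had 58187149 UMIs over all barcodes and kept 6427 cells with 54006249 UMIs. Median depth was 4846 UMIs per barcode in the control library and 7351 in the light-damaged library. All intervals are 95% intervals that cover counting error only. Group and library cannot be told apart in this design.

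The first comparison asked which myeloid cells the gate held in each library. Microglia-like cells were the most numerous class in both, at 83.0% of kept cells in the control library (interval 81.7% to 84.1%) and 71.9% in the light-damaged library (70.8% to 73.0%). Monocyte- or macrophage-like cells, which used monocyte markers such as Ccr2, the receptor for monocyte-attracting chemokines, were 1.07% of control cells (0.771% to 1.45%, 41 cells) and 17.4% of light-damaged cells (16.5% to 18.3%, 1117 cells). Perivascular-macrophage-like cells, which line vessels and use the mannose receptor gene Mrc1, were 5.47% of control cells (4.77% to 6.24%) and 2.18% of light-damaged cells (1.84% to 2.57%). The remaining 10.5% of control cells (9.54% to 11.5%) and 8.53% of light-damaged cells (7.85% to 9.24%) lay in clusters left unnamed. The YFP gate and the depth gap between the libraries can set all of these shares, and they are shares of sorted cells, not of retinal cells.

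**Figure D1:**
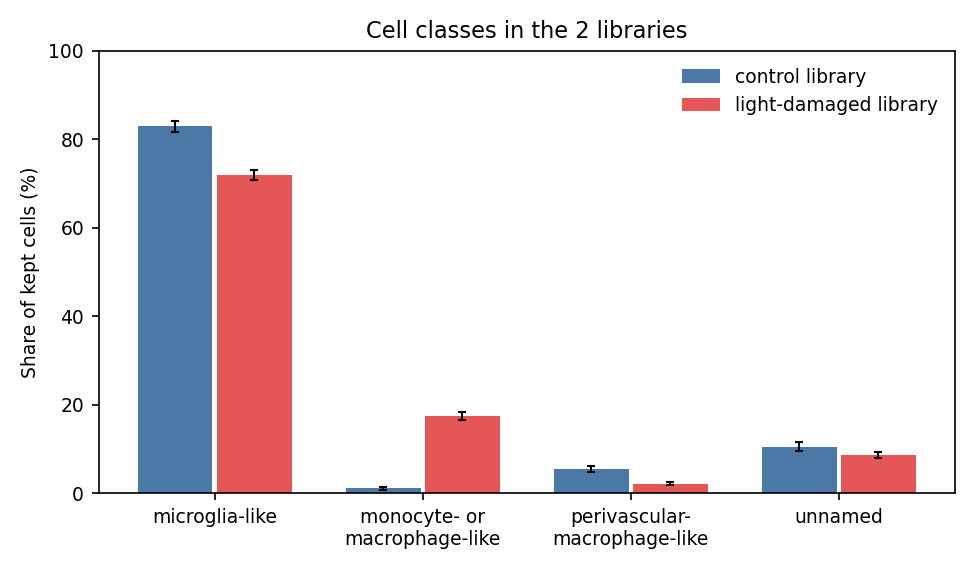
Share of kept cells (%) in each named class and in unnamed clusters, for the control library (3820 cells) and the light-damaged library (6427 cells); bars are shares and error bars are exact 95% binomial intervals that cover counting error only. Monocyte- or macrophage-like cells were 1.07% of the control library and 17.4% of the light-damaged library.

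The monocyte- or macrophage-like class joined 3 clusters. Cluster 3, led by Gpnmb, Ms4a7 and Acp5, held 37 control and 932 light-damaged cells. Cluster 11, led by the inducible myeloid genes Tnfsf9, Clec4e and Il1b, held 3 and 131 cells, and cluster 16, led by the cell division genes Ube2c and Birc5, held 1 and 54 cells. Among unnamed clusters, cluster 10 was led by rod photoreceptor transcripts such as Gngt1 and Pdc and kept microglia markers (101 control and 48 light-damaged cells), and cluster 18 was led by bipolar cell transcripts (20 and 10 cells). Cluster 17 mixed markers of vascular cells and Müller glia (22 and 11 cells). No cluster was named after dendritic cells, neutrophils, T cells, NK cells, B cells, rods, cones, Müller glia or astrocytes, bipolar, amacrine or ganglion cells, pigment epithelium, endothelium, pericytes or erythrocytes. For each of these names, the upper limit for a count of 0 was 0.0965% of the 3820 control cells and 0.0574% of the 6427 light-damaged cells. The limit covers cells in named clusters only. It does not bound cells of these types in unnamed clusters, such as the vascular and glial cells that cluster 17 may hold. For rods and bipolar cells the count of 0 holds under the rule in use only. The second naming rule named 101 control and 48 light-damaged cells as rods, and both other rules named 20 and 10 cells as bipolar cells. With the first naming rule at resolution 1.2 the light-damaged monocyte- or macrophage-like share was 3.81% and the control share 0.236%. With the second rule at that resolution the control microglia-like share was 49.8%, and 39.3% of control cells were named rods.

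The main comparison asked how transcripts of microglia-like cells differed between the libraries, over 4622 light-damaged cells with 33671237 UMIs and 3169 control cells with 15944471 UMIs. Microglia-like cells of the light-damaged library had higher levels of genes of lipid handling, of the interferon response and of the disease-associated microglia state, and lower levels of several genes of the homeostatic state. Apoe, the main lipid carrier protein of glia, was at 2119 CPM in the control library and 10100 CPM in the light-damaged library, 4.77-fold higher (4.71 to 4.82). Ifi27l2a, an interferon-induced gene, was 8.43-fold higher (8.08 to 8.79), at 143 and 1207 CPM. Lgals3, which encodes the glycan-binding protein galectin-3, was 16.6-fold higher (14.3 to 19.4), at 11.4 and 188 CPM. P2ry12, a purinergic receptor gene and a marker of resting microglia, was 1.91-fold lower (1.89 to 1.94), at 2456 and 1284 CPM. Most control cells of the class lay in clusters 2 and 8 (2777 and 316 cells), and most light-damaged cells in clusters 1, 4 and 5 (3056, 865 and 398 cells).

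Among the 12 genes with the highest ratio were also Vim, an intermediate filament gene, at 12.1-fold (10.4 to 14.1), Spp1, which encodes the secreted protein osteopontin, at 8.01-fold (7.30 to 8.80), and Irf7, a transcription factor of the interferon response, at 10.4-fold (8.77 to 12.3). The others were Fabp5, a fatty acid-binding protein gene, at 7.42-fold, Lgals3bp, which encodes a galectin-binding protein, at 6.88-fold, Ifitm3, an interferon-induced membrane protein gene, at 6.67-fold, the chemokine genes Ccl5 at 5.53-fold and Ccl12 at 4.11-fold, and the non-coding transcript Zfos1 at 4.11-fold. A small cluster of 88 light-damaged and 6 control cells, led by Mmp12 and Lgals3 and keeping 2 of the 10 microglia markers, held 77.95% of the Lgals3 UMIs of light-damaged microglia-like cells, 54.0% of those of Fabp5, 49.6% of those of Vim and 37.2% of those of Spp1. Without this cluster, Lgals3 was 4.93-fold higher (4.14 to 5.92), Vim 6.39-fold (5.48 to 7.48), Spp1 5.17-fold (4.70 to 5.69) and Fabp5 4.36-fold (3.58 to 5.35). With no doublets removed Spp1 had a log2 ratio of 3.875, against 3.0016 in the main setting.

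In mm10, Lgals3 (ENSMUSG00000050335) is a protein-coding gene on chromosome 14 from 47367751 to 47386160 on the plus strand. Apoe (ENSMUSG00000002985) lies on chromosome 7 from 19696109 to 19699188 on the minus strand. Ifi27l2a (ENSMUSG00000079017) lies on chromosome 12 from 103442167 to 103443680 on the minus strand, and Spp1 (ENSMUSG00000029304) on chromosome 5 from 104435118 to 104441050 on the plus strand. P2ry12 (ENSMUSG00000036353) lies on chromosome 3 from 59216272 to 59262871 on the minus strand. All are annotated as protein-coding, and the UMIs were counted per gene from 3' end libraries.

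Of the genes with the lowest ratio, Ier5, an immediate-early response gene, was 6.40-fold lower in the light-damaged library (6.22 to 6.598), at 1095 and 171 CPM. Cebpa, a myeloid transcription factor gene, was 4.98-fold lower (4.68 to 5.30), and the nuclear receptor coactivator gene Pnrc1 was 5.04-fold lower (4.73 to 5.37). Gstp1, which encodes a detoxifying glutathione transferase, was 4.92-fold lower, Bcas3 4.05-fold lower and the nucleic acid-binding protein gene Ybx1 3.50-fold lower. The predicted genes Gm10073, Gm10116 and Gm10076 were 4.06-fold, 4.07-fold and 3.57-fold lower, and they share from 56.6% to 69.9% of their last 50-base words with transcripts of other genes, so their counts are uncertain. The rod transducin gene Gngt1 was 8.30-fold lower (7.09 to 9.75), at 48.8 and 5.88 CPM. This rod transcript was measured in cells named microglia-like.

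**Figure D2:**
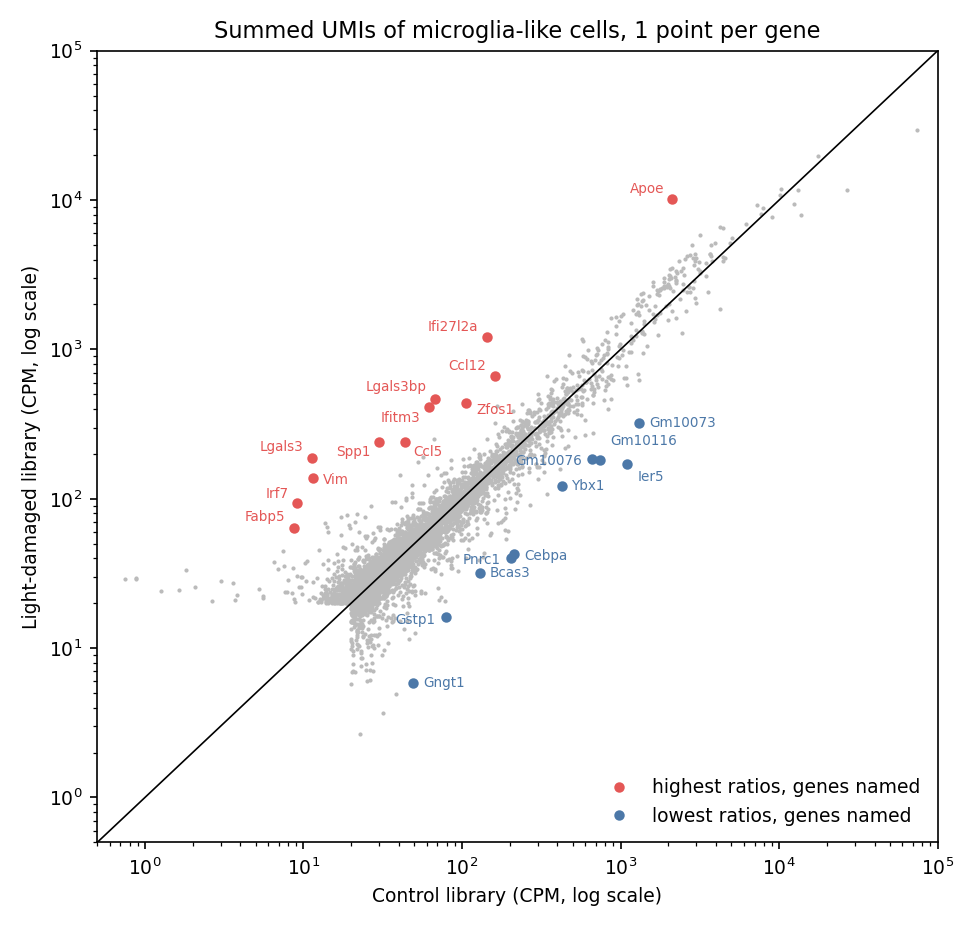
CPM of reported genes with at least 20 CPM in either library, summed over microglia-like cells, in the control library (x axis, log scale) and the light-damaged library (y axis, log scale); 1 point per gene, the line marks equal values and colours mark the named genes with the highest and the lowest ratios. Apoe lies at 2119 and 10100 CPM and Ier5 at 1095 and 171 CPM.

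Genes were then grouped by the 18 lists. The type I interferon list, genes that cells switch on after interferon signalling, had all 18 measured members over 1.5 times higher in the light-damaged library. Its median log2 ratio was 1.87 (counting interval 1.74 to 1.97), above 100% of matched random lists. Besides Ifi27l2a, Irf7 and Ifitm3, the DNA-sensing gene Ifi204 was 4.19-fold higher (3.71 to 4.74). The antiviral genes Oasl2, Rsad2 and Zbp1 were 7.69-fold, 4.88-fold and 5.80-fold higher, and Cxcl10, an interferon-induced chemokine gene, was 1.52-fold higher. The MHC class I list, which covers antigen presentation to cytotoxic T cells, had a median of 0.55 (0.54 to 0.57) at the 99.98th percentile of random lists. Of its 8 measured members 3 were over 1.5 times higher and 0 lower, with Tap1, a peptide transporter gene, at 2.27-fold and H2-D1, a class I heavy chain gene, at 1.66-fold.

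The disease-associated microglia list, genes raised in microglia around lesions, had 24 measured members, of which 12 were over 1.5 times higher, 1 lower and 11 within that range. Its median log2 ratio was 0.60 (0.52 to 0.61), above 100% of random lists, and 17 of its genes also stood on another list. Higher members included Cst7, a cysteine protease inhibitor gene, at 4.57-fold (3.98 to 5.27), and Gpnmb, which encodes a lysosomal glycoprotein, at 19.3-fold (12.4 to 31.8) from 1.25 to 24.2 CPM. The receptor genes Trem2 and Tyrobp were at ratios of 0.909 and 0.904, and Timp2, a protease inhibitor gene, was 1.51-fold lower. The lipid handling list had 9 measured members, 6 of them over 1.5 times higher and 0 lower, and a median of 0.98 (0.77 to 1.19). Its median was 1.80 with a minimum of 50 CPM, 1.70 with the first naming rule at resolution 1.2 and 0.66 with a pseudocount of 10 CPM. Its members included Lpl, which encodes lipoprotein lipase, at 5.06-fold (4.40 to 5.84), and Plin2, which coats lipid droplets, at 2.54-fold (2.33 to 2.77). Without the Mmp12-led cluster Plin2 was 1.55-fold higher and Gpnmb 6.81-fold (4.28 to 11.5). The log2 ratio of Gpnmb was 4.27 in the main setting, 3.36 with no doublets removed and 3.20 with the stricter cell filter.

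The homeostatic microglia list had 20 measured members, 6 of them over 1.5 times lower in the light-damaged library, 1 higher and 13 within that range. Its median was -0.41 (-0.43 to -0.39), below all 10000 random lists, and it contains the 10 markers used to name the class. Cst3, a cysteine protease inhibitor gene, was 2.53-fold lower (2.52 to 2.53), at 74169 and 29352 CPM. It was also lower in perivascular-macrophage-like cells, at 15699 and 7490 CPM, where the median of the homeostatic list was -0.07. P2ry13, a purinergic receptor gene, was 1.999-fold lower (1.94 to 2.06), and the receptor gene Gpr34 was 1.88-fold lower. Tmem119, a microglia surface marker, was 1.40-fold lower (1.37 to 1.42), while Cx3cr1 and Csf1r, the receptor for the main microglial survival signals, were at ratios of 0.929 and 0.891. Fcrls, an Fc receptor-like gene, was 3.76-fold higher (3.53 to 4.01). The myeloid transcription factor list had a median of -0.21 (-0.25 to -0.14), with 0 of 14 members over 1.5 times higher and 3 lower, among them Cebpa and Klf4.

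The list of secreted trophic and regulatory factors had 8 measured members, 4 of them over 1.5 times higher and 0 lower, with a median of 0.89 (0.76 to 1.01). Hbegf, an epidermal growth factor-like ligand gene, was 4.40-fold higher (3.88 to 5.00), Il1rn, which encodes an antagonist of interleukin-1, 3.11-fold (2.62 to 3.71), and Gdf15, a stress-induced cytokine gene, 2.37-fold (2.06 to 2.75). Without the Mmp12-led cluster Gdf15 was 1.29-fold higher and the median of this list was 0.46. The cell cycle list had 6 of 8 measured members over 1.5 times higher and 0 lower, with a median of 2.16 (1.96 to 2.40). Top2a, which untangles DNA in dividing cells, was 18.4-fold higher (12.7 to 27.6), Birc5, needed for cell division, 38.8-fold (22.1 to 75.3), and Cdk1, the mitotic kinase gene, 9.29-fold (6.95 to 12.7). The cell cycle median was 0.0012 without the cycling cluster of 75 light-damaged cells and 1 control cell, 0.20 with the mean of CPM per cell and -0.0086 with the stricter cell filter. With that filter the log2 ratios were 1.72 for Top2a, 3.98 for Birc5 and 1.55 for Cdk1, against 4.20, 5.28 and 3.22 in the main setting.

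The immediate-early and heat-shock list, genes switched on within minutes by stress or tissue handling, had 5 of 17 members over 1.5 times lower in the light-damaged library and 0 higher. Its median was -0.26 (-0.29 to -0.23), at the 0.17th percentile of random lists. Klf2, a transcription factor gene, was 3.21-fold lower (3.03 to 3.39), and Jun, a component of the AP-1 transcription factor, 2.29-fold lower (2.27 to 2.32). The MHC class II list, which covers antigen presentation to helper T cells, had 5 measured members, 2 of them over 1.5 times lower and 0 higher, and a median of -0.50 (-0.58 to -0.44). Its median was 0.083 when response genes were kept in the clustering and 1.03 with the first naming rule at resolution 1.2. Cd74, the class II invariant chain gene, was 1.60-fold lower (1.51 to 1.69), at 141 and 88.3 CPM. In perivascular-macrophage-like cells Cd74 was at 11777 and 738 CPM. Free RNA, which adds UMIs to cells that do not use a gene, may thus hold part of this fall, which was not tested. H2-DMa, 1.33-fold lower, was at 403 CPM in control microglia-like cells and 360 CPM in control perivascular-macrophage-like cells.

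Other lists had medians nearer to 0. The list of inflammatory cytokines and NF-kB targets had a median of 0.16 (0.13 to 0.20), with 5 of 14 members over 1.5 times higher and 0 lower. Among these were Cxcl16 at 1.84-fold, Tnf at 1.75-fold (1.67 to 1.83) and Il1b at 1.63-fold, while the chemokine genes Ccl3 and Ccl4 were at ratios of 0.905 and 0.969. The complement list had a median of 0.07 (0.07 to 0.08), and C4b, a component of the classical pathway, was 15.03-fold higher (10.2 to 23.1) from 1.63 to 24.5 CPM. The C1q chain genes C1qa, C1qb and C1qc were at ratios of 1.06, 1.05 and 1.11. The lysosome list had a median of 0.03 (0.02 to 0.04), with Grn, which encodes progranulin, 1.74-fold higher and Lamp1, a lysosomal membrane protein gene, 1.61-fold lower. The list for oxidative stress and iron had a median of 0.33 (0.29 to 0.35), with Srxn1, which reduces oxidised peroxiredoxins, at 2.20-fold (1.93 to 2.51). Glycolysis had a median of 0.20 (0.17 to 0.24), with Pgk1 3.92-fold lower and Pkm 1.51-fold higher, and oxidative phosphorylation one of 0.03 (0.0040 to 0.06), with 12 of 12 members within 1.5 times. Migration and cytoskeleton genes had a median of 0.06 (0.04 to 0.08), with Lgals1 2.30-fold higher and Tmsb10 1.82-fold lower. Phagocytic and pattern receptors had a median of -0.0012 (-0.08 to 0.01), with Axl, a receptor for dying cells, 2.36-fold higher (2.20 to 2.53).

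In all, 5 of the 18 lists had a median over 1.5-fold from equal levels, all of them higher in the light-damaged library. That number was 3 without the Mmp12-led cluster, at resolution 0.3, with the mean of CPM per cell and with a minimum of 50 CPM, and 8 with the first naming rule at resolution 1.2.

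**Figure D3:**
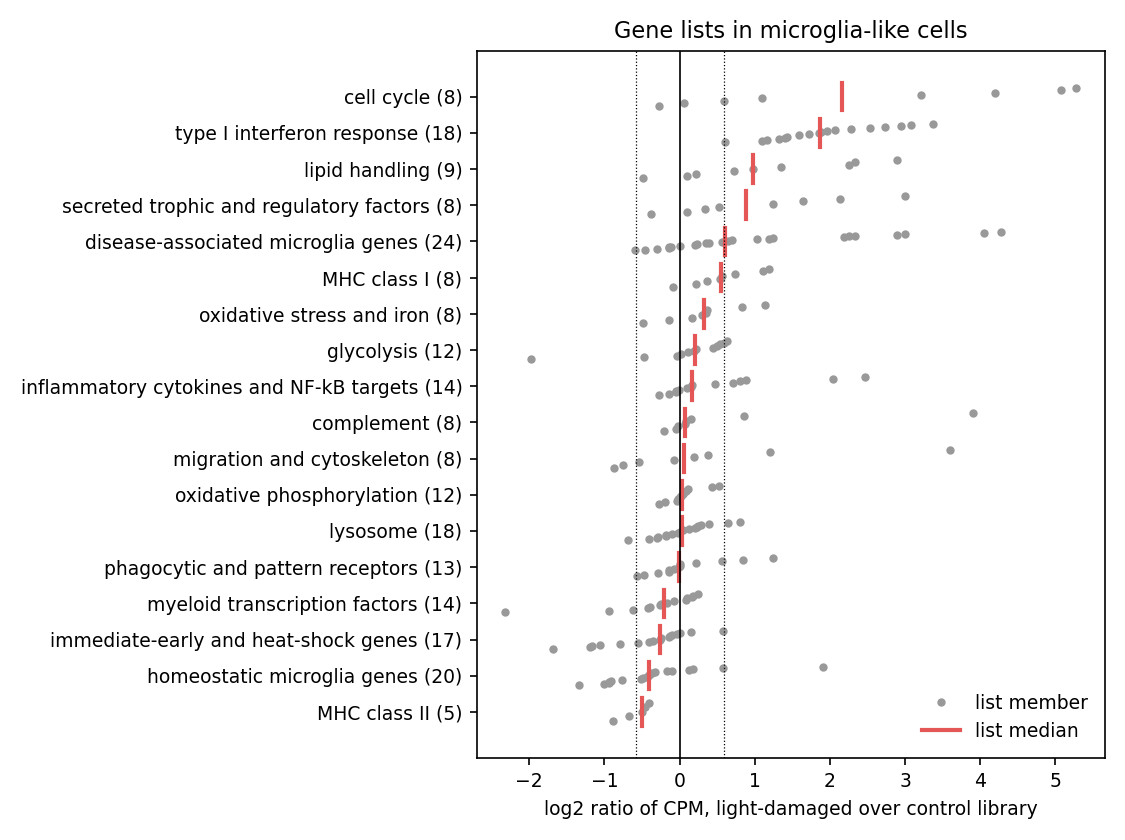
Log2 ratio of CPM in microglia-like cells, light-damaged over control library, for the 18 gene lists; grey points are members with at least 20 CPM in either library, their number is in brackets, red bars are medians and dotted lines mark 1.5-fold. The interferon list has its median at 1.87 and the homeostatic list at -0.41.

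Shares of cells were compared at 2700 UMIs per cell, which left out 302 shallow control cells. Among microglia-like cells, 98.1% of control cells and 91.4% of light-damaged cells had a UMI of P2ry12 (97.5% to 98.6% and 90.5% to 92.2%). Apoe was seen in 88.7% (87.5% to 89.9%) and 98.2% (97.8% to 98.6%), Spp1 in 3.66% (3.005% to 4.42%) and 13.7% (12.7% to 14.7%), Lpl in 3.24% and 12.3%, and Cst7 in 2.13% and 9.78%. Lgals3 was seen in 1.50% (1.09% to 2.02%) and 8.96% (8.15% to 9.82%), and together with P2ry12 in 1.33% (0.940% to 1.81%) and 6.71% (6.003% to 7.47%). Without thinning, Lgals3 together with P2ry12 was seen in 2.46% of control and 15.9% of light-damaged cells. Cx3cr1 was seen in 88.0% and 86.4%, and Mki67, a marker of dividing cells, in 0.105% and 1.17%.

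Free RNA adds UMIs to cells that do not use a gene. P2ry12 was seen in 40.8% of control and 27.1% of light-damaged perivascular-macrophage-like cells, at median depths of 7292 and 9183 UMIs before thinning, against 5109 and 6697 in microglia-like cells. Lgals3 was seen in 7.28% and 17.1% of perivascular-macrophage-like cells, and together with P2ry12 in 3.40% (1.38% to 6.88%) and 6.43% (2.98% to 11.9%). The joint share in microglia-like cells was below that of perivascular-macrophage-like cells in the control library and near it in the light-damaged library. Perivascular-macrophage-like cells had Lgals3 at 51.1 and 103 CPM, against 11.4 and 188 CPM in microglia-like cells, and may use the gene themselves. Their joint share is thus no measure of background for microglia-like cells. Whether the higher joint share of light-damaged microglia-like cells lies above background cannot be told, and it is not read as such a difference. Spp1 was seen in 9.71% and 45.7% of perivascular-macrophage-like cells, Cst7 in 0.971% and 7.14%, and Lpl in 0.971% and 1.43%. No class here was known to lack Lgals3 or Apoe, so their background was not measured.

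Microglia-like cells were clustered again without the genes of any list, to see whether sub-clusters differed in the left-out lists. All 9 sub-clusters were over 90% from 1 library, and 0 sub-clusters had 50 cells of both, so none was compared between libraries. The largest light-damaged sub-cluster, number 1 (3032 cells), had summed homeostatic genes at 58813 CPM (58712 to 58915) and interferon genes at 2456 CPM (2435 to 2477). The control sub-clusters 2 and 3 (1534 and 1250 cells) had homeostatic genes at 115260 and 104940 CPM and interferon genes at 656 and 574 CPM. Cst3 alone was at 74169 CPM over control and 29352 CPM over light-damaged microglia-like cells. The homeostatic sums thus follow this 1 gene to a large part, and 13 of the 20 members were within 1.5 times between the libraries. Lipid handling genes were at 11128 CPM in sub-cluster 1 and at 1928 and 2289 CPM in sub-clusters 2 and 3. Apoe alone was at 10730.0 CPM in sub-cluster 1 and at 1587 and 2023 CPM in sub-clusters 2 and 3.

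Smaller sub-clusters stood apart in 1 or more lists. Sub-cluster 8 (88 light-damaged cells, 7 control cells) had disease-associated genes at 89961 CPM (89366 to 90558), the highest of the 9, and homeostatic genes at 11946 CPM (11730.0 to 12165), the lowest. In its light-damaged cells Lgals3 was at 5079 CPM, Spp1 at 3100.1 CPM and P2ry12 at 137 CPM, against 28.4, 82.6 and 1456 CPM in sub-cluster 1. Its complement genes were at 6328 CPM against 29240.0 CPM in sub-cluster 1, and its median mitochondrial share was 0.343% against 2.76%. Sub-cluster 7 (135 light-damaged cells) had interferon genes at 14032 CPM (13818 to 14248) and sub-cluster 9 (75 light-damaged cells) cell cycle genes at 10022 CPM (9856 to 10190.0). Related genes outside the lists could still shape the clustering. Ifit3b was among the leading genes of sub-cluster 7, and Pbk and Cdca8 among those of sub-cluster 9. These high list values are thus not independent of the clustering. Sub-cluster 5 (399 light-damaged and 42 control cells) had inflammatory and NF-kB genes at 41719 CPM in its light-damaged cells, against 2380.0 CPM in sub-cluster 1. Immediate-early and heat-shock genes were at 66008 CPM in sub-cluster 6 (322 control cells) and 43839 CPM in sub-cluster 4 (854 light-damaged cells).

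**Figure D4:**
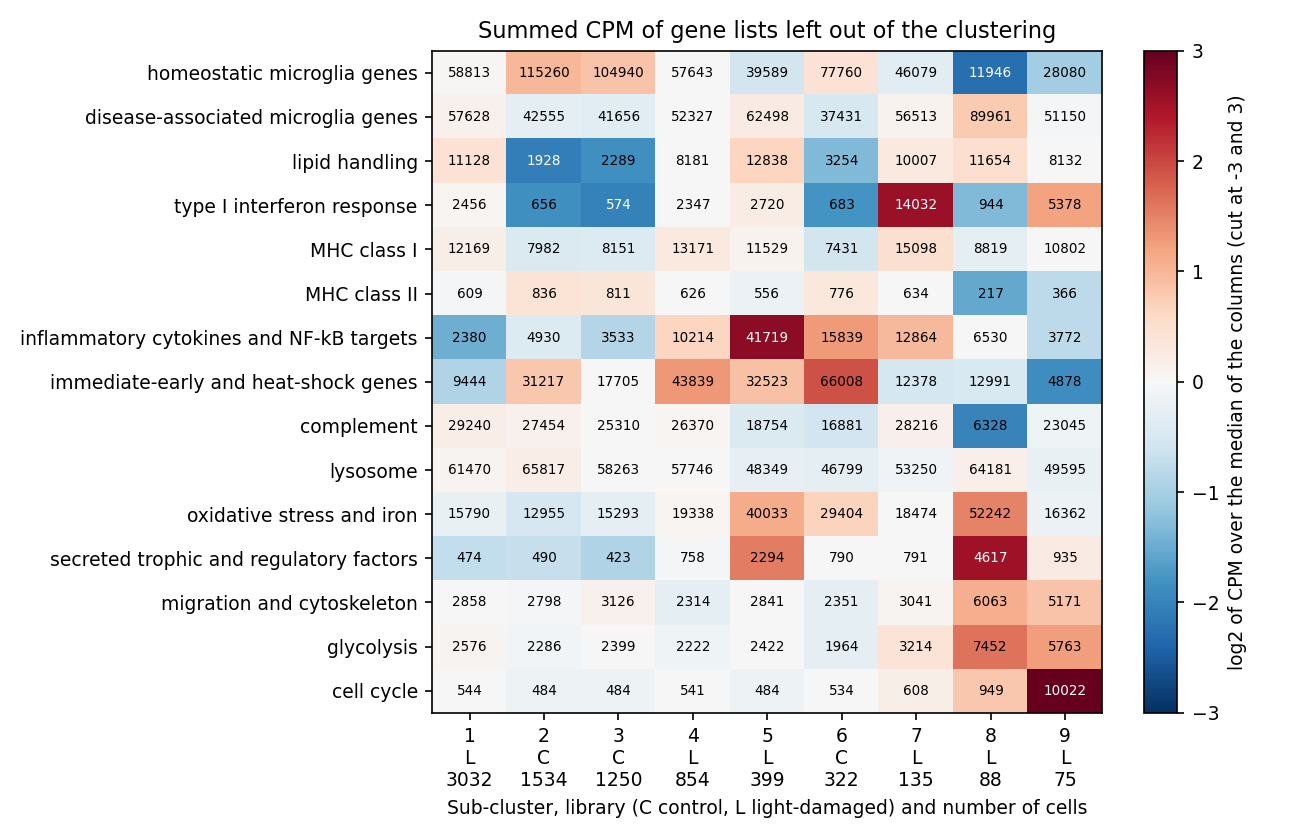
Summed CPM of each gene list (numbers) in sub-clusters of microglia-like cells, for the library with most of each sub-cluster's cells; the colour is the log2 of CPM over the median of the 9 columns, cut at -3 and 3. Sub-cluster 8 has the highest sum of disease-associated genes, 89961 CPM, and the lowest of homeostatic genes, 11946 CPM.

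Within the light-damaged library, the 1117 monocyte- or macrophage-like cells were set beside the 4622 microglia-like cells, since the control library held fewer than 50 such cells. Monocyte- or macrophage-like cells had far higher MHC class II transcripts, with a list median of 4.81 on the log2 scale (4.78 to 4.85) and 5 of 6 members over 1.5 times higher. H2-Aa and H2-Eb1, class II chain genes, were 136-fold (123 to 150.3) and 129-fold (116 to 145) higher, and Cd74 52.7-fold (50.8 to 54.7). Gpnmb was 25.6-fold higher (23.8 to 27.6) and Spp1 10.7-fold (10.5 to 11.0). The homeostatic list had 19 of 20 members over 1.5 times lower and a median of -1.76 (-1.82 to -1.73), and as it holds the microglia markers used for naming, part of this follows from the class names. Adgrg1, an adhesion receptor gene, was 27.1-fold lower (22.0 to 33.8), the crystallin gene Crybb1 17.3-fold and the actin-bundling gene Fscn1 17.2-fold lower. Pmp22, Cd34 and Selplg, which encodes a selectin ligand, were 10.9-fold, 12.4-fold and 7.03-fold lower. Lists of migration, lipid handling, cell cycle and interferon genes had medians of 1.76, 1.48, 1.11 and 0.89. The migration list holds S100a6, Ahnak and Crip1, monocyte markers used for naming, so part of its median may follow from the class names. Apart from these markers, the genes named here had not shaped the clustering.

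The third comparison took perivascular-macrophage-like cells, 140 light-damaged cells with 1292498 UMIs and 209 control cells with 1584841 UMIs. MHC class II genes were lower in the light-damaged library, with 6 of 6 measured members over 1.5 times lower and a list median of -4.20 (-4.33 to -4.07), below all 10000 random lists. H2-Aa was 27.1-fold lower (22.5 to 32.9), at 2390.1 and 88.2 CPM, H2-Eb1 25.3-fold (20.4 to 31.7), H2-Ab1 21.3-fold (18.0 to 25.2) and Cd74 16.0-fold (14.9 to 17.0), at 11777 and 738 CPM. Class limits may enter this result. Cluster 11 (131 light-damaged and 3 control cells) had H2-Eb1 and H2-Aa among its leading genes. It had 3 perivascular macrophage and 7 monocyte markers that counted, so it went to the monocyte- or macrophage-like class. Over all kept cells the class II median was -0.10. List medians of perivascular-macrophage-like cells were not computed under the alternative settings. Ccl8, a chemokine gene, was 58.8-fold higher (33.4 to 114), at 7.57 and 445 CPM, and Saa3, an acute-phase protein gene, 36.0-fold (23.1 to 59.5). C4b was 8.61-fold higher (6.35 to 11.9), the C-type lectin gene Clec4d 5.66-fold (4.28 to 7.57) and the non-coding B930036N10Rik 15.4-fold (6.28 to 49.2). Serpinb2, a protease inhibitor gene, had 0 UMIs in control cells and was at least 20.8-fold higher. The non-coding A330069E16Rik, with 1 UMI in light-damaged cells, was 94.6-fold lower (16.6 to 3768).

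Other lists in perivascular-macrophage-like cells had smaller medians. Interferon genes had a median of 0.85 (0.69 to 1.09), with 13 of 17 members over 1.5 times higher and 0 lower, and disease-associated genes one of 0.65 (0.60 to 0.70), with 14 of 23 higher and 0 lower. Immediate-early and heat-shock genes had a median of -0.68 (-0.77 to -0.63), with 10 of 17 members over 1.5 times lower and 0 higher. Complement and lysosome genes had medians of 0.52 and 0.39. Scaling by the median ratio of genes, in place of total UMIs, would shift every log2 ratio of this class by 0.11. In mm10, H2-Aa (ENSMUSG00000036594) lies on chromosome 17 from 34282744 to 34287823 on the minus strand and Ccl8 (ENSMUSG00000009185) on chromosome 11 from 82115185 to 82116799 on the plus strand; both are protein-coding.

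The last comparison took all kept cells, whatever their class, and so mixes composition with expression. Spp1 was 17.3-fold higher in the light-damaged library (16.3 to 18.4), Fabp5 22.4-fold (19.6 to 25.7), Gpnmb 34.3-fold (28.1 to 42.4), Lgals3 17.5-fold (15.8 to 19.4), Vim 10.5-fold (9.50 to 11.7) and Ifi27l2a 8.22-fold (7.94 to 8.52). Among the lowest were Ier5 at 7.48-fold lower, together with the rod genes Gngt1 at 11.4-fold (10.7 to 12.1), Pde6g at 9.57-fold and Pdc at 10.1-fold lower. Over all kept cells the MHC class II median was -0.10, with 6 of 6 members within 1.5 times, and H2-Aa had a log2 ratio of 0.40 against -0.88 in microglia-like cells. The median of inflammatory and NF-kB genes was -0.12 over all kept cells.

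Markers of cell types outside the sorted classes were also measured over all kept cells. Sag, which encodes rod arrestin, was at 166 and 33.1 CPM in the control and light-damaged libraries. The cone genes Pde6h and Opn1sw were at 19.3 and 14.9 CPM in the control library and at 2.9997 and 2.94 CPM in the light-damaged library, and the bipolar genes Pcp2 and Cabp5 were 3.85-fold and 4.88-fold lower. Glul, which encodes glutamine synthetase of Müller glia, was at 807 and 494 CPM over all kept cells and at 810.0 and 614 CPM in microglia-like cells. Haemoglobin gene Hba-a1 was at 6.60 and 0.0185 CPM. Endothelial Cldn5 and Ly6c1 were at 12.8 and 11.4 CPM in the control library and 4.26 and 5.02 CPM in the light-damaged library, and pericyte Rgs5 at 13.9 and 5.04 CPM. Of lymphocyte markers, Lck was at 1.94 and 0.704 CPM, Klrd1 at 1.36 and 0.204 CPM and Cd79b at 12.4 and 14.1 CPM. Ccr7 of dendritic cells was at 0.367 and 4.26 CPM and S100a8 of neutrophils at 0.262 and 1.09 CPM, while Csf3r was at 128 and 119 CPM. Amacrine Tfap2b, ganglion cell Rbpms and pigment epithelial Rdh5 were at 0.524, 5.82 and 2.93 CPM in the control library and at 0.49994, 3.68 and 1.70 CPM in the light-damaged library.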

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

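Cluster 6 held 6.04% of light-damaged cells (388 cells, interval 5.47% to 6.65%) and 0.236% of control cells (9 cells, 0.108% to 0.447%). It kept 10 of the 10 microglia markers and was led by Fn1, Cst7 and Psat1. It stayed unnamed because Fn1, which encodes fibronectin, is a monocyte marker, and so it was left out of the class comparisons. Its median depth was 12471 UMIs per cell. In its light-damaged cells disease-associated genes summed to 90883 CPM (90624 to 91143), lipid handling genes to 21582 CPM and homeostatic genes to 30502 CPM. Cell cycle genes summed to 1777 CPM. Which class these cells belong to is open.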

How the results depend on the processing

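In the main setting microglia-like cells were 83.0% of control and 71.9% of light-damaged cells, and monocyte- or macrophage-like cells 1.07% and 17.4%. List medians (log2) were -0.41 for homeostatic, 0.60 for disease-associated and 1.87 for interferon genes. These 3 lists were picked as headline results among the 18. Values listed below lay outside the counting interval of the main value or had the other sign, and counts of lists differed from 5. The causes were not tested. The stricter cell filter gave shares of microglia-like cells of 86.7% and 69.7%, and medians of -0.38 for homeostatic, -0.0086 for cell cycle and -0.028 for oxidative phosphorylation genes. Without a cell filter, these shares were 85.7% and 79.0% and the homeostatic median -0.47. With no doublets removed the light-damaged microglia-like share was 77.8% and the homeostatic median -0.48. Resolution 0.3 gave 69.6%, -0.36 for homeostatic and -0.032 for oxidative phosphorylation genes, and 3 lists over 1.5-fold. The first naming rule at resolution 0.3 gave the same 4 values. The second rule there gave them too, with a light-damaged monocyte- or macrophage-like share of 15.3%. Resolution 1.2 gave a control microglia-like share of 86.5%, a light-damaged monocyte- or macrophage-like share of 15.2% and a homeostatic median of -0.46. The first rule at resolution 1.2 gave microglia-like shares of 87.5% and 84.3% and monocyte- or macrophage-like shares of 0.236% and 3.81%. Medians were then -0.60 for homeostatic and 1.03 for MHC class II genes, with 8 lists over 1.5-fold. The second rule at resolution 1.2 gave a control microglia-like share of 49.8% and a light-damaged monocyte- or macrophage-like share of 16.4%. Medians were then -0.51 for homeostatic, 1.62 for interferon and -0.0026 for lysosome genes, with 3 lists. With response genes kept in the clustering, the control microglia-like share was 85.4% and the light-damaged monocyte- or macrophage-like share 15.9%, with medians of -0.46 for homeostatic and 0.083 for MHC class II genes. The second rule at resolution 0.6 gave a light-damaged microglia-like share of 70.7% and medians of -0.39 for homeostatic, 0.62 for disease-associated and -0.023 for oxidative phosphorylation genes. The mean of per-cell CPM gave 1.66 for interferon, -0.010 for lysosome and -0.017 for oxidative phosphorylation genes, and 3 lists. The disease-associated median was 0.69 with no expression minimum and 0.48 with a 50 CPM minimum, which left 3 lists. A pseudocount of 10 CPM gave 0.49 for disease-associated and 1.28 for interferon genes. All kept cells gave medians of -0.63 for homeostatic, 0.66 for disease-associated, 1.74 for interferon and -0.12 for inflammatory genes, and log2 ratios of 0.40 for H2-Aa, 0.016 for H2-Ab1, -0.090 for Srxn1 and 0.021 for Uqcrb. With unnamed clusters of microglia profile added the homeostatic median was -0.48, and with control cells at the light-damaged minimum depth -0.37. Without the interferon-led cluster the interferon median was 1.62. Without the Mmp12-led cluster, medians were -0.39 for homeostatic and -0.0012 for lysosome genes, with 3 lists. Without the cycling cluster they were -0.39 for homeostatic, 0.62 for disease-associated and -0.023 for oxidative phosphorylation genes. The share with Lgals3 together with P2ry12, 1.33% and 6.71% in the main setting, was 2.46% and 15.9% without thinning and 0.37999% and 2.86% at 0.5 of the depth. Shares of perivascular-macrophage-like cells stayed inside the counting interval of the main value under every setting, from 5.26% to 5.71% in the control library and from 1.96% to 2.21% in the light-damaged library. Of list medians, 195 moved, 14 reversed and 205 stayed the same. Of log2 ratios of single genes, 197 moved, 4 reversed and 351 stayed the same.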

Other observations

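Monocyte- or macrophage-like cells of cluster 3 came from both libraries, though only 37 were from the control library, too few for a comparison under the limits set here. In those control cells MHC class II genes summed to 34004 CPM and in the 932 light-damaged cells to 7335 CPM. Homeostatic genes summed to 30425 and 14097 CPM in the same cells, and lipid handling genes to 93180.0 and 78471 CPM. The light-damaged cells of cluster 14, the Mmp12-led cluster counted as microglia-like, had genes of oxidative stress and iron at the highest level of the microglia-like sub-clusters, 52242 CPM in sub-cluster 8 against 15783 CPM in cluster 1. Other sub-clusters also lay above cluster 1, with 40033 CPM in light-damaged cells of sub-cluster 5 and 29404 CPM in control cells of sub-cluster 6.

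The first pattern is the 10 lowest genes of light-damaged microglia-like cells, with rod transcripts left out; the test in perivascular-macrophage-like cells was chosen only after the result was seen. Sequence shared with other genes could misplace reads, but 4 of these 10 genes had over 50% shared (random lists: median 0, upper 97.5% bound 2), so it is not the whole cause. For those 4 genes, near-identical genes were higher by 41.1% of the missing CPM, which leaves moved reads undecided. Bias by GC content is unlikely, since genes of like GC content had a median log2 ratio of 0.020 against -2.16 for these genes. Perivascular-macrophage-like cells had a median of -1.85 for the same genes, which is what a library-wide difference, in the mice or in sample handling, would give.

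The second pattern is the higher interferon list in light-damaged microglia-like cells; the tests on free RNA and on a small cluster were chosen only after the result was seen, and the alternative by depth was added once the data had been examined. With only the 2695 control cells at or above the light-damaged minimum depth, the median was 1.85, against 1.87. Shallow cells add few UMIs to summed counts, so leaving them out could hardly move the median. The test therefore cannot exclude the depth gap between the libraries as a cause. Free RNA from monocyte- or macrophage-like cells would have to make up 39.2% of the RNA of microglia-like cells, while the class II genes H2-Aa and H2-Eb1 allow at most 0.774%. Without the small interferon-led cluster the median was still 1.62. A response to the light and a difference between the 2 pools or libraries both remain, and a second pair of pools could separate them.

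The third pattern is the higher rod transcripts in control microglia-like cells; the test of free RNA was chosen only after the result was seen. If free RNA from rods were the cause, perivascular-macrophage-like cells should hold as much, and their median log2 ratio over microglia-like cells was 1.08, a value that leaves free RNA undecided. Within the microglia-like class, rod RNA in a minority of cells is unlikely to be the whole cause. The 5% of its control cells with the most held 22.9% of rod UMIs, against 16.8% under even spread. Cluster 10 (101 control cells) was led by rod transcripts, kept 10 microglia markers and was left unnamed, so this test did not include it. The test therefore cannot judge whether a minority of cells had engulfed rods. Fewer surviving rods in the light-damaged retina would lower free rod RNA, and a count of rods in the same mice could test that.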
